A study of Mus musculus with 46 samples.

How the data were processed

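Per the labels, macrophages were grown from mouse bone marrow, RNA was extracted with Qiagen RNeasy Plus columns, and stranded TruSeq libraries of polyadenylated RNA were made. The 46 libraries were pooled and sequenced on 3 lanes of a NovaSeq 6000 as single reads of 100 nt. The authors demultiplexed with bcl2fastq 2.20 and quantified with kallisto 0.44.0 on GRCm38. The deposited values are estimated counts, which the authors computed with kallisto per transcript and summarised per gene before deposit, and the labels do not say whether a correction for transcript length was applied in that step. Of the values above 0, 11.7% lay within 0.02 of a whole number. Estimated counts were rounded for the tests, which changed no library's total by more than 133 counts.

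The deposited table held 24671 genes, each given by its Ensembl identifier. GENCODE M21 supplied symbols and GRCm38 positions for 24243 of them, and the other 428 held 0.483% of the counts. No pair of libraries was identical. Between replicates of a group, the chi-square per degree of freedom of genes with at least 40 counts in the pair ran from 3.91 to 12.2 over 95 pairs, where counting error alone would give about 1.

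Genes with enough counts were kept with edgeR's filterByExpr, which left 13838. Scaling factors were computed by TMM, and edgeR 4.0.16 fitted its quasi-likelihood model with robust settings to all 46 libraries with 1 mean per group, leaving 37 residual degrees of freedom. Differences and interactions were tested as contrasts of those means, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common dispersion was 0.00571, a biological coefficient of variation of 7.55%. Levels are TMM-scaled CPM. The 95% intervals of single genes are the log2 fold change with its standard error times the t quantile at 37 degrees of freedom.

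Counts were simulated for all 46 libraries at their depths, from gene means over all libraries and a spread that depended on the mean level only. In the 27HC group 200 genes were changed, drawn from genes above a minimum expected count, and 13644 genes were tested. Against Vehicle, the same test recovered 70% of 50 genes changed 1.25-fold and 90% of those changed 1.5-fold. It recovered 94% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls among 13444 unchanged genes. These shares do not cover genes with few counts or with a larger spread than others of their level.

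The gene lists cover LXR targets, fatty acid synthesis, cholesterol synthesis and uptake, estrogen-responsive genes, inflammatory cytokines and NF-kB targets, the interferon response, alternative activation, MHC class II and co-stimulation, MHC class I and peptide loading, T cell-inhibiting myeloid genes, the cell cycle, glycolysis and hypoxia, the unfolded protein and integrated stress response, NRF2 targets, PPAR targets and lipid droplets, macrophage identity, immediate early genes and mitochondrially encoded transcripts. They also cover markers of neutrophils, lymphocytes, dendritic cells, stromal cells, erythroid cells, mast cells and basophils, and osteoclasts. Some genes belong to several lists, so results of such lists are not separate. Among them are Scd2 and Fasn (LXR targets and fatty acid synthesis) and Slc7a11 (stress response and NRF2 targets). Camera in limma 3.58.1 tested the 23 lists with at least 3 tested members on log2 CPM, with a preset correlation of 0.01 between genes and again with a correlation estimated per list, and adjusted over those 23 lists within a comparison. Among 143 called list results, 0 medians changed sign under 9 other ways of processing.

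The groups, tests, lists, rule for named genes and all alternatives but the one without mitochondrially encoded genes were fixed before the data were examined. Tests of explanations were chosen later, and some genes that the rule takes were left out after the results were seen. The rule takes, in each comparison, the receptor genes Nr1h2, Nr1h3, Esr1 and Esr2, up to 4 members with the smallest p of each list described, and from the 6 highest and 6 lowest log2 fold changes among called genes with a mean CPM of at least 1 and no overlap between the groups compared. The overlap condition was dropped for interactions, and predicted genes and immunoglobulin or T cell receptor segments were passed over. Genes named for 27HC against Vehicle were allowed again in combinations and interactions, and a few more genes, among them Abca1, Abcg1, Srebf1, Mylip and Hmgcs1, in every group. For 5 libraries the labels disagree on the compound added to GW3965, so it was left unnamed, and no label was changed from the values.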

Results

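Bone marrow-derived macrophages (BMDM) of mice, cells grown from bone marrow into macrophages in culture, were exposed to ligands of the liver X receptors (LXR) or the estrogen receptors (ER), and their polyadenylated RNA was sequenced in 46 libraries. LXR are nuclear receptors that sense oxysterols and switch on genes of cholesterol export and lipid synthesis. Vehicle was given to 6 libraries, and each of 8 treatments to 5. The single compounds were 27-hydroxycholesterol (27HC), an oxysterol that binds LXR and ER, GW3965, a synthetic LXR agonist, GSK2033, an LXR antagonist, estradiol (E2), an ER agonist, and ICI, the ER antagonist fulvestrant. The combinations were GSK2033 with 27HC, ICI with 27HC, and GW3965 with a second compound. For the last, the titles name 27HC and the source and treatment labels name ICI, so that second compound is left unnamed. Doses and times of exposure are not in the labels. Total estimated counts per library ran from 19354093 to 30921038, and group means ran from 22597879 ± 1785341 (SD, n = 5) with ICI plus 27HC to 24717020 ± 2968726 (SD, n = 5) with GW3965 plus the second compound. Mitochondrially encoded transcripts took 1.6% ± 0.102 (SD, n = 6) of the counts with Vehicle, 2.17% ± 0.119 (SD, n = 5) with GW3965, the highest group mean, and 1.34% ± 0.113 (SD, n = 5) with GSK2033 plus 27HC, the lowest.

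Throughout, log2 fold changes carry their standard error, levels are in CPM (counts scaled to 1000000 per library) with SD, and Vehicle has n = 6 and every other group n = 5. Each adjusted p of a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13838 genes, and each adjusted p of a gene list is from camera with a preset correlation. Counts of list members are over all genes tested. The same counts adjusted over the list alone stand in brackets where they differ, and were otherwise identical. For each gene given with its own value and said to have changed between a pair of groups, every library of the first group lay beyond every library of the other, apart from those named. Genes in brackets behind a count of 5 or fewer were chosen after their values were seen, unless the rule for named genes takes them too. Nothing in the labels says whether libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

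The genes followed in every group were protein-coding in the annotation of the GRCm38 genome. Abcg1 (ENSMUSG00000024030, chromosome 17, 31057675 to 31117988, plus strand) and Abca1 (ENSMUSG00000015243, chromosome 4, 53030787 to 53159895, minus strand) encode transporters that move cholesterol out of macrophages. Abcg1 stood at 41.2 ± 7.25 CPM with Vehicle, 342 ± 15.7 with 27HC, 976 ± 43.0 with GW3965, 1.34 ± 0.236 with GSK2033 and 0.737 ± 0.145 with GSK2033 plus 27HC. Abca1 stood at 394 ± 32.7 CPM with Vehicle, 988 ± 64.0 with 27HC, 2037 ± 174 with GW3965 and 71.3 ± 8.80 with GSK2033. Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260, plus strand), which acts early in cholesterol synthesis, stood at 75.3 ± 2.36 CPM with Vehicle, 29.2 ± 1.76 with 27HC, 55.5 ± 2.35 with GW3965 and 37.5 ± 1.01 with GSK2033. Srebf1 (ENSMUSG00000020538, chromosome 11, 60199089 to 60222581, minus strand), which drives fatty acid synthesis, stood at 69.8 ± 3.18 CPM with Vehicle, 79.4 ± 4.24 with 27HC and 363 ± 8.18 with GW3965. Of the receptors, Nr1h3 (LXR alpha, ENSMUSG00000002108, chromosome 2, 91184061 to 91202834, minus strand) stood at 71.3 ± 3.33 CPM and Nr1h2 (LXR beta, ENSMUSG00000060601, chromosome 7, 44549616 to 44553951, minus strand) at 81.3 ± 2.1 CPM with Vehicle. Esr1 (ER alpha, ENSMUSG00000019768, chromosome 10, 4611593 to 5005614, plus strand) stood at 6.18 ± 0.320 CPM, and Esr2 (ER beta, ENSMUSG00000021055), with 0 to 7 counts per library, was not tested.

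**Figure D1:**
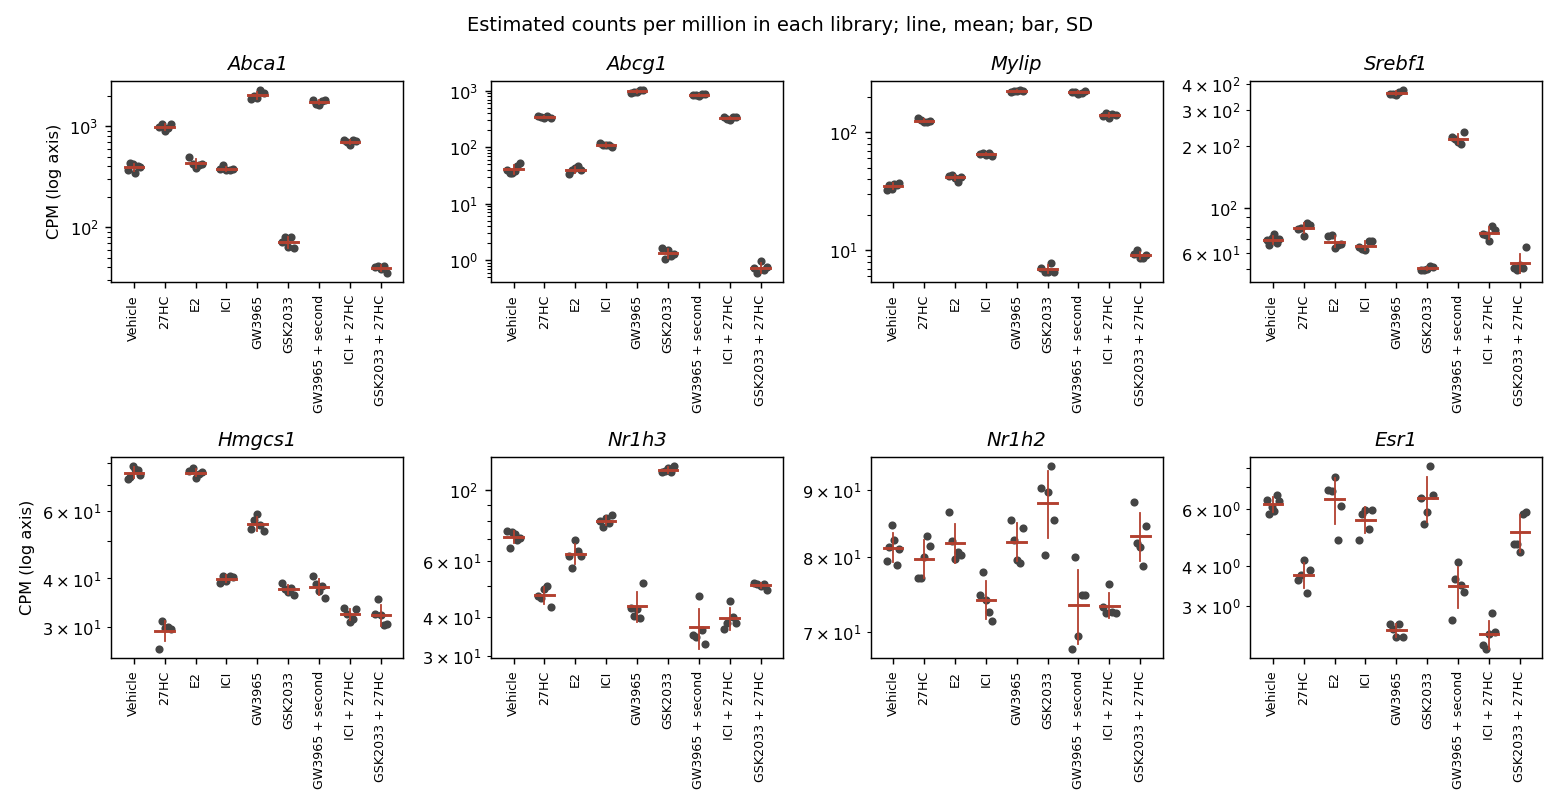
Levels of 8 genes in the 9 groups in CPM on a logarithmic axis, with a point per library, a line at the mean and a bar for the SD. Abcg1 and Abca1 are highest with GW3965 and lowest with GSK2033 plus 27HC, and Hmgcs1 is lowest with 27HC.

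**Figure D2:**
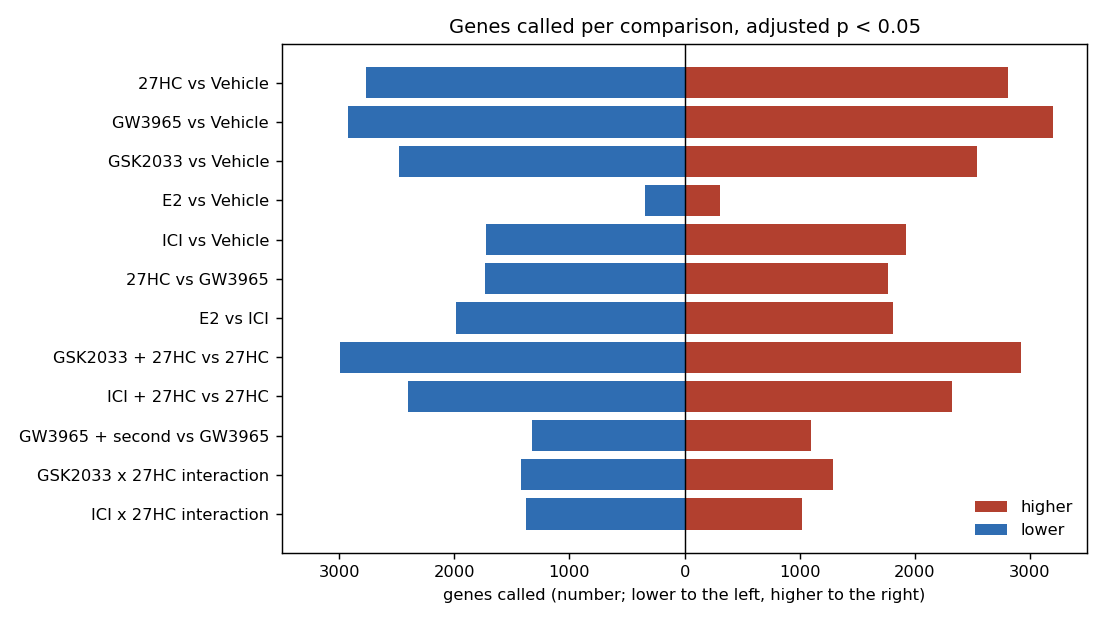
Number of genes lower (left bars) and higher (right bars) at an adjusted p under 0.05 in each comparison, of 13838 genes tested. E2 against Vehicle has the fewest, 650, and GW3965 against Vehicle the most, 6123.

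The 27HC libraries were compared with Vehicle to ask what this oxysterol does alone. LXR targets rose with 27HC, while genes of cholesterol synthesis and uptake, of the interferon response and of MHC class I and II fell. Abcg1 rose 8.31-fold (log2 3.06 ± 0.069, adjusted p = 1.49e-33), and Mylip, a ubiquitin ligase gene, rose 3.57-fold (log2 1.84 ± 0.035, adjusted p = 4.30e-37). Idi1, an isomerase gene of cholesterol synthesis, fell 5.60-fold (log2 -2.49 ± 0.056, adjusted p = 2.62e-34). Irf7, a transcription factor of the interferon response, fell 4.27-fold (log2 -2.1 ± 0.044, adjusted p = 4.10e-35), and H2-K1, an MHC class I chain that shows peptides to T cells, fell 2.36-fold (log2 -1.24 ± 0.031, adjusted p = 1.66e-32). Abca1 rose as well (1.33 ± 0.063 on the log2 scale), and the receptor genes Nr1h3 (-0.61 ± 0.061) and Esr1 (-0.73 ± 0.11) fell, while Nr1h2 had a log2 fold change of -0.03 ± 0.036 and Srebf1 of 0.19 ± 0.049 (adjusted p = 0.00159), with overlapping libraries. High changes beyond these were in Plau (1.86 ± 0.044), which activates plasminogen, the elastase gene Mmp12 (1.80 ± 0.037), Nptx1 (1.76 ± 0.070) and Dusp4 (1.66 ± 0.061), a phosphatase of MAP kinases. Low ones were in Ms4a4c (-4.69 ± 0.15), Slfn1 (-4.44 ± 0.13), the guanylate-binding protein gene Gbp4 (-3.42 ± 0.36) and the interferon-induced Ifit3b (-3.20 ± 0.084).

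Of LXR targets with 27HC, 13 of 18 rose and 2 fell (Nr1h3 and Smpdl3a), median 0.48, adjusted p = 1.11e-08. Scd2, a fatty acid desaturase, rose by 1.61 and Arl4c by 0.76 on the log2 scale. Among cholesterol synthesis and uptake genes, 23 of 25 fell and 0 rose, median -1.12, adjusted p = 1.54e-27. Examples were Insig1 (-1.71 ± 0.036), which holds back sterol regulation, and Hmgcs1 (-1.37 ± 0.039). In the fatty acid synthesis list, 7 of 15 rose and 5 fell (Fads1, Fads2, Me1, Acly and Acss2), median 0.19, adjusted p = 0.285. For the interferon response, 26 of 26 fell and 0 rose, median -1.86, adjusted p = 3.91e-41, with Ifit1 at -2.54 ± 0.066. Among MHC class I and peptide loading genes, 13 of 15 fell and 1 rose (Calr), median -0.96, adjusted p = 4.38e-17, and of MHC class II and co-stimulation genes, 9 of 12 fell and 0 rose (10 and 0 adjusted over the list alone), median -0.67, adjusted p = 6.89e-07, with H2-Ab1 at -0.98 ± 0.045 and Cd74, the invariant chain, at -0.61 ± 0.038. Reads can be shared between the paralogs H2-Q4 and H2-Q7 of the class I list, so their values are uncertain. Among inflammatory cytokines and NF-kB targets, 9 of 21 fell and 4 rose (Ccl4, Tnfaip3, Cxcl2 and Tnf, or 10 and 6 adjusted over the list alone), median -0.39, adjusted p = 0.103, with Ccl5, a chemokine for T cells, at -1.88 ± 0.047 and Il1b, a cytokine of inflammation, at -2.58 ± 0.17.

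Cell cycle genes rose with 27HC as a list: 14 of 26 rose and 0 fell, median 0.31, adjusted p = 1.08e-04. Pcna, the clamp of DNA polymerases, rose by 0.85 and Mcm6, part of the replicative helicase, by 0.78. Of unfolded protein and integrated stress response genes, 12 of 19 rose and 2 fell (Sesn2 and Ddit3), median 0.33, adjusted p = 6.64e-07, with the chaperone gene Hspa5 at 0.49 ± 0.022. Of NRF2 targets, 7 of 12 rose and 0 fell, median 0.18, adjusted p = 1.57e-05, with Hmox1, which breaks down heme, at 0.54 ± 0.024. Of estrogen-responsive genes, 8 of 15 rose and 3 fell (Cxcl12, Esr1 and Fhl2, or 10 and 3 adjusted over the list alone), median 0.19, adjusted p = 0.00292. Ccnd1, a cyclin that promotes entry into the cell cycle, rose by 1.02 and Igf1, a growth factor, by 0.69. Of immediate early genes, 7 of 12 rose and 3 fell (Klf2, Junb and Ier3), median 0.39, adjusted p = 0.00462, with Jun at 0.61 ± 0.025. Of T cell-inhibiting myeloid genes, 9 of 15 fell and 4 rose (Havcr2, Vegfa, Nt5e and Il10), median -0.33, adjusted p = 0.0168 (adjusted p = 0.0921 with an estimated correlation). Siglec1, a sialic acid receptor, fell by 1.86 on the log2 scale, and Havcr2, a checkpoint receptor also called Tim-3, rose by 0.72. Of macrophage identity genes, 10 of 13 fell and 2 rose (among them Cd68), median -0.21, adjusted p = 7.31e-04, with Adgre1, which encodes F4/80, at -1.10 ± 0.030. Lists not called included PPAR targets and lipid droplets, where 7 of 12 rose and 4 fell (Fabp5, Pdk4, Cpt1a and Ucp2), median 0.17, adjusted p = 0.0717, with the scavenger receptor gene Cd36 at 1.26 ± 0.025, glycolysis and hypoxia, where 10 of 18 rose and 4 fell (Pfkfb3, P4ha1, Adm and Hk2), median 0.11, adjusted p = 0.0735, and alternative activation, where 5 of 13 rose (Pparg, Trem2, Mrc1, Stab1 and Il10) and 3 fell (Il4ra, Socs3 and Ccl22), median 0.08, adjusted p = 0.361. Il10 was not called (0.33 to 0.46) without Vehicle replicate 2, 3, 5 or 6 or 27HC replicate 1 or 3.

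In total 2812 genes rose and 2764 fell with 27HC, among them 127 that rose and 387 that fell at least 2-fold, and camera called 14 of 23 lists, 11 with an estimated correlation. Stromal markers differed between the same groups, where 6 of 9 fell and 1 rose (Pdgfrb), median -0.35, adjusted p = 0.00127 (adjusted p = 0.0921 with an estimated correlation), with Sparc at -0.37 ± 0.030 and Col3a1, a collagen gene, at -0.81 ± 0.075. Mitochondrial transcripts made up 1.90% ± 0.0980 (SD, n = 5) of counts with 27HC against 1.6% ± 0.102 (SD, n = 6) with Vehicle, and of their genes 9 of 13 rose and 0 fell, median 0.33, adjusted p = 0.00170 (adjusted p = 0.298 with an estimated correlation).

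GW3965 was compared with Vehicle to measure the response to a synthetic LXR agonist. LXR targets and fatty acid synthesis genes, lists that share members such as Scd2, rose with GW3965. Interferon, inflammatory and antigen presentation genes fell. Abcg1 rose 23.7-fold (log2 4.57 ± 0.072, adjusted p = 6.64e-40), and Scd2 rose 24.8-fold (log2 4.63 ± 0.043, adjusted p = 9.34e-50). Srebf1 rose 5.20-fold (log2 2.38 ± 0.048, adjusted p = 6.05e-37). Il1b fell 33.5-fold (log2 -5.07 ± 0.21, adjusted p = 9.78e-24), and Irf7 fell 10.9-fold (log2 -3.45 ± 0.048, adjusted p = 2.38e-42). Abca1 (2.37 ± 0.064), Mylip (2.66 ± 0.035), Lpcat3 (2.05 ± 0.033), which inserts polyunsaturated chains into phospholipids, Scd1 (3.47 ± 0.079) and Eepd1 (3.18 ± 0.048) rose too, and so did the less abundant Lbp (3.03 ± 0.33), which binds bacterial lipopolysaccharide. Nr1h3 (-0.73 ± 0.061) and Esr1 (-1.29 ± 0.11) fell, and Nr1h2 had a log2 fold change of 0.02 ± 0.036. Among the lowest changes were Ms4a4c (-6.16 ± 0.18) and Adgre4 (-4.85 ± 0.17), an adhesion receptor gene. Slfn1, Mcemp1 and Vnn3 fell to 0.110 ± 0.0580, 0.00713 ± 0.0160 and 0.0356 ± 0.0209 CPM, too near 0 for a firm fold change.

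Of LXR targets, 16 of 18 rose and 1 fell (Nr1h3), median 2.08, adjusted p = 6.11e-20. Of fatty acid synthesis genes, 14 of 15 rose and 0 fell, median 1.12, adjusted p = 2.18e-14. Cholesterol genes went both ways: 7 of 25 fell and 6 rose, median 0.02, adjusted p = 0.826. Insig1 rose by 0.70, and Idi1 had -0.61 ± 0.050 and Hmgcs1 -0.44 ± 0.037. Of inflammatory genes, 20 of 21 fell and 1 rose (Tnfaip3), median -1.59, adjusted p = 7.01e-12, with Saa3, an acute phase gene, at -3.76 ± 0.18 and Ccl5 at -2.79 ± 0.050. Of interferon response genes, 26 of 26 fell and 0 rose, median -2.56, adjusted p = 9.39e-41. Of MHC class II genes, 10 of 12 fell and 0 rose, median -0.71, adjusted p = 5.97e-07, with Cd86, which co-stimulates T cells, at -1.65 ± 0.075. Of MHC class I genes, 14 of 15 fell and 1 rose (Calr), median -1.11, adjusted p = 2.81e-15, with H2-T23 at -1.79 ± 0.038. Of T cell-inhibiting genes, 9 of 15 fell and 2 rose (Tgfb1 and Havcr2), median -0.58, adjusted p = 3.87e-04, with Siglec1 at -3.14 ± 0.072.

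Stress and antioxidant genes rose with GW3965: 15 of 19 rose and 3 fell (Slc7a11, Ddit3 and Sesn2), median 0.48, adjusted p = 1.87e-09 for the stress response, and 11 of 12 rose and 1 fell (Slc7a11), median 1.08, adjusted p = 3.86e-15 for NRF2 targets. Mthfd2, a mitochondrial folate enzyme, rose by 1.11, Hmox1 by 1.49 and Cat, which encodes catalase, by 1.30. Of PPAR targets and lipid droplet genes, 7 of 12 rose and 0 fell, median 0.14, adjusted p = 1.83e-04, with Cd36 at 1.46 ± 0.025. Of macrophage identity genes, 10 of 13 fell and 3 rose (among them Mertk and Cd68), median -0.36, adjusted p = 3.35e-06, with Cd14, a lipopolysaccharide co-receptor gene, at -2.34 ± 0.042. Cell cycle genes were not called as a list (median -0.05, adjusted p = 0.718), nor were immediate early genes, where 5 of 12 rose (Atf3, Egr2, Egr1, Jun and Fosb) and 5 fell (Fos, Ier2, Ier3, Junb and Zfp36), median 0.01, adjusted p = 0.782, although Pcna rose by 1.31. In total 3201 genes rose and 2922 fell, among them 213 that rose and 554 that fell at least 2-fold, and camera called 14 of 23 lists, 12 with an estimated correlation. Stromal markers differed, where 7 of 9 fell and 0 rose, median -0.37, adjusted p = 2.83e-04 (adjusted p = 0.0650 with an estimated correlation), with Cxcl12, a chemokine of stromal cells, at -1.10 ± 0.035. Of mitochondrial transcripts, 11 of 13 rose and 0 fell (12 and 0 adjusted over the list alone), median 0.60, adjusted p = 1.41e-05 (adjusted p = 0.150 with an estimated correlation).

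27HC was set directly against GW3965 because the series title asks whether ligands modulate LXR selectively. With 27HC, LXR targets, fatty acid synthesis genes and cholesterol genes were lower than with GW3965, and inflammatory and interferon genes were higher. Insig1 was 5.32-fold lower (log2 -2.41 ± 0.037, adjusted p = 9.29e-41), at 21.5 ± 0.739 against 114 ± 2.51 CPM. Scd2 was 8.09-fold lower (log2 -3.02 ± 0.042, adjusted p = 2.07e-42), and Srebf1 was 4.57-fold lower (log2 -2.19 ± 0.050, adjusted p = 7.03e-34). Cd14 was 4.12-fold higher (log2 2.04 ± 0.043, adjusted p = 2.93e-35), and Cxcl2, a chemokine for neutrophils, was 4.96-fold higher (log2 2.31 ± 0.13, adjusted p = 1.19e-18). Abcg1 (-1.51 ± 0.066) and Abca1 (-1.04 ± 0.065) were lower with 27HC, as were Fads2 (-3.39 ± 0.11), a fatty acid desaturase, and Scd1 (-2.94 ± 0.082). Saa3 (2.97 ± 0.18), the siderophore binder gene Lcn2 (3.53 ± 0.28) and the platelet chemokine gene Ppbp (3.66 ± 0.21) were higher. Esr1 was higher (0.56 ± 0.12), and Nr1h3 (0.12 ± 0.065, adjusted p = 0.196) and Nr1h2 (-0.04 ± 0.038, adjusted p = 0.467) were not called, although Nr1h3 was (0.20) without GW3965 replicate 5.

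Of LXR targets, 15 of 18 were lower and 0 were higher, median -1.02, adjusted p = 3.69e-29. Of fatty acid synthesis genes, 14 of 15 were lower and 0 were higher, median -0.88, adjusted p = 1.40e-27. Of cholesterol genes, 22 of 25 were lower and 0 were higher, median -1.02, adjusted p = 1.19e-41, with Srebf2, the main activator of cholesterol synthesis, at -1.49 ± 0.042. Of inflammatory genes, 17 of 21 were higher and 0 were lower, median 1.29, adjusted p = 3.24e-16. Of interferon response genes, 23 of 26 were higher and 0 were lower (25 and 0 adjusted over the list alone), median 0.77, adjusted p = 1.36e-28, with Irf7 at 1.35 ± 0.046. Of T cell-inhibiting genes, 8 of 15 were higher and 2 were lower (Tgfb1 and Cd274, or 10 and 2 adjusted over the list alone), median 0.29, adjusted p = 6.46e-05, with Ptges, a prostaglandin E synthase gene, at 1.55 ± 0.12. Of cell cycle genes, 15 of 26 were higher and 1 was lower (Pcna), median 0.33, adjusted p = 5.14e-05.

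Of NRF2 targets, 11 of 12 were lower and 1 was higher (Slc7a11), median -0.67, adjusted p = 2.16e-23, with Cat at -1.16 ± 0.022. Of stress response genes, 13 of 19 were lower and 3 were higher (Slc7a11, Xbp1 and Ddit3, or 13 and 4 adjusted over the list alone), median -0.17, adjusted p = 5.46e-06. Of PPAR targets, 9 of 12 were lower and 1 was higher (Hilpda), median -0.18, adjusted p = 7.65e-05. Of macrophage identity genes, 9 of 13 were higher and 2 were lower (among them Mertk), median 0.23, adjusted p = 3.80e-06, with Itgam, an integrin chain also called CD11b, at 0.99 ± 0.038. Of immediate early genes, 7 of 12 were higher and 2 were lower (Atf3 and Klf2, or 9 and 2 adjusted over the list alone), median 0.32, adjusted p = 5.62e-05. In total 1765 genes were higher and 1735 lower with 27HC, among them 197 higher and 103 lower at least 2-fold, and camera called 16 of 23 lists, 13 with an estimated correlation. With library totals only, without scaling factors, 60.9% of the called genes were higher, against 50.4% with them. The mitochondrial transcripts had a list median of -0.28 (adjusted p = 0.00434, or adjusted p = 0.306 with an estimated correlation). Ddit3 was not called (0.14 to 0.15) without 27HC replicate 1, 2 or 4 or GW3965 replicate 3 or 4.

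Across 13295 genes, which are not independent replicates, the log2 fold changes of 27HC and GW3965 against Vehicle had a Pearson r of 0.746 and a covariance of 0.186. Both comparisons use the same Vehicle libraries, and unchanged groups simulated with those libraries gave a mean r of 0.454 and a covariance of 0.0112, a difference of 0.175 in covariance. With the Vehicle libraries split 3 and 3, so that no library served both comparisons, r was 0.622 on average over 20 splits (0.593 to 0.646), with a covariance of 0.172. In these splits both compounds raised 1483.6 genes on average, where independent calls would give 419.19, and both lowered 1498.8, where independent calls would give 424.99, while 156 moved in opposite directions. With all Vehicle libraries in both comparisons, both raised 1939 genes, both lowered 1918, and 186 moved in opposite directions. Insig1 (27HC -1.71, GW3965 0.70) was far from equality of both responses, and Irf7 (-2.1 and -3.45) was low in both.

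**Figure D3:**
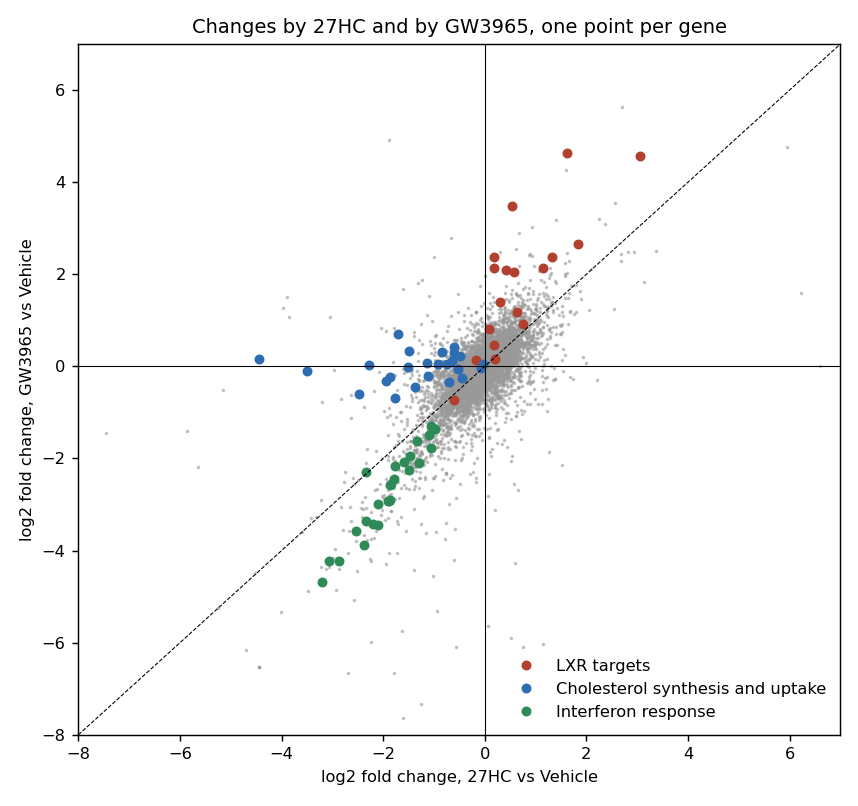
Log2 fold change against Vehicle with 27HC (horizontal) and with GW3965 (vertical), with a point per gene and a dashed line of equality. LXR targets (red) mostly lie above the line, interferon genes (green) are low on both axes, and cholesterol genes (blue) are low with 27HC and on both sides of 0 with GW3965.

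GSK2033 was compared with Vehicle to measure an LXR antagonist in the absence of added agonist. LXR targets, fatty acid synthesis and cholesterol genes fell with GSK2033, while interferon and stress response genes rose. Abcg1 fell 30.6-fold (log2 -4.94 ± 0.13, adjusted p = 6.42e-31), and Abca1 fell 5.52-fold (log2 -2.46 ± 0.070, adjusted p = 2.11e-29). Idi1 fell 4.47-fold (log2 -2.16 ± 0.055, adjusted p = 5.65e-32), and Mylip fell 5.08-fold (log2 -2.35 ± 0.046, adjusted p = 2.19e-36). Cxcl10, an interferon-induced chemokine, rose 5.15-fold (log2 2.36 ± 0.13, adjusted p = 1.54e-19), and Trib3, a target of the stress response, rose 3.58-fold (log2 1.84 ± 0.051, adjusted p = 1.95e-30). Nr1h3 rose by 0.70 and Nr1h2, with overlapping libraries, by 0.11, and Esr1 had a log2 fold change of 0.07 ± 0.10 (adjusted p = 0.643). Without GSK2033 replicate 4 the Nr1h2 value was 0.09 and not called. Other high changes were in H2-M2 (2.29 ± 0.070), Hcar2 (2.17 ± 0.12), Gdf15 (1.94 ± 0.047), a stress-induced cytokine, Aqp9 (2.36 ± 0.23), a water and glycerol channel, and Cox6a2 (2.04 ± 0.18). Eepd1 (-2.62 ± 0.071) was among the low changes.

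Of LXR targets, 15 of 18 fell and 2 rose (Nr1h3 and Cd5l), median -0.74, adjusted p = 1.70e-18. Of fatty acid synthesis genes, 12 of 15 fell and 2 rose (Acss2 and Me1), median -0.47, adjusted p = 9.82e-10. Of cholesterol genes, 22 of 25 fell and 0 rose (23 and 1 adjusted over the list alone), median -0.83, adjusted p = 2.73e-27, with Sqle, the epoxidase of the pathway, at -1.6 ± 0.051. Of interferon response genes, 23 of 26 rose and 1 fell (Irf7), median 0.65, adjusted p = 4.23e-14, with Rsad2, an antiviral enzyme also called viperin, at 1.04 ± 0.048. Of MHC class I genes, 14 of 15 rose and 0 fell, median 0.35, adjusted p = 6.10e-12, and of MHC class II genes, 6 of 12 rose and 2 fell (H2-DMb2 and H2-DMa, or 7 and 2 adjusted over the list alone), median 0.21, adjusted p = 0.0223 (adjusted p = 0.0822 with an estimated correlation), with Cd40 at 1.18 ± 0.079. Of inflammatory genes, 15 of 21 rose and 3 fell (Saa3, Il1b and Il1a), median 0.74, adjusted p = 1.08e-08 (adjusted p = 0.0822 with an estimated correlation). The chemokine genes Ccl4 (1.82 ± 0.052) and Ccl3 (1.72 ± 0.075) and Tnf (1.05 ± 0.065) rose. Of stress response genes, 18 of 19 rose and 0 fell, median 0.57, adjusted p = 5.09e-23, with Atf4, its transcription factor, at 0.89 ± 0.027. Of NRF2 targets, 10 of 12 rose and 1 fell (Osgin1), median 0.40, adjusted p = 3.12e-11, with Slc7a11, which imports cystine, at 1.58 ± 0.077. Of macrophage identity genes, 10 of 13 fell and 1 rose (Cd68), median -0.35, adjusted p = 7.53e-09. Cd5l was not called (0.09 to 0.12) without Vehicle replicate 1, 2, 3, 5 or 6 or GSK2033 replicate 1, 3, 4 or 5. Me1 was not called (0.14) without Vehicle replicate 1 or GSK2033 replicate 1.

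In total 2542 genes rose and 2483 fell with GSK2033, among them 120 that rose and 128 that fell at least 2-fold, and camera called 13 of 23 lists, 8 with an estimated correlation. T cell-inhibiting genes were not called as a list, where 7 of 15 rose and 6 fell, median -0.01, adjusted p = 0.824, with Vsir, a checkpoint ligand also called VISTA, at -0.70 ± 0.040 and Cd274, which encodes PD-L1, at 0.72 ± 0.052. Stromal markers differed, where 5 of 9 fell (Pdgfrb, Postn, Col3a1, Cxcl12 and Sparc) and 0 rose, median -0.16, adjusted p = 0.00338 (adjusted p = 0.149 with an estimated correlation), with Pdgfrb at -0.57 ± 0.054. Mitochondrial transcripts took 1.37% ± 0.0960 (SD, n = 5) of counts with GSK2033, and of their genes 9 of 13 fell and 0 rose (10 and 0 adjusted over the list alone), median -0.28, adjusted p = 0.00407 (adjusted p = 0.349 with an estimated correlation).

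E2 was compared with Vehicle to measure an ER agonist, and changed the fewest genes. Interferon response and MHC class I genes fell with E2, and NRF2 targets rose. Ms4a4c fell 2.29-fold (log2 -1.19 ± 0.11, adjusted p = 1.21e-10), and Rsad2 fell 1.65-fold (log2 -0.73 ± 0.050, adjusted p = 2.05e-14). F13a1, a clotting factor chain made by macrophages, rose 1.97-fold (log2 0.98 ± 0.072, adjusted p = 1.23e-13), and Tgm2, a transglutaminase, rose 1.77-fold (log2 0.83 ± 0.028, adjusted p = 6.97e-26). Nr1h2 (0.01 ± 0.036), Nr1h3 (-0.18 ± 0.060, adjusted p = 0.0776) and Esr1 (0.06 ± 0.10, adjusted p = 0.864) were not called, nor were Abca1 (0.13 ± 0.063) and Abcg1 (-0.04 ± 0.074). Nr1h3 was called without E2 replicate 3 (-0.22), with library totals only (-0.19) and with a replicate block (-0.18). Aldh1a2 (0.63 ± 0.087), an enzyme of retinoic acid synthesis, and N4bp3 (0.67 ± 0.12) rose, and Slfn1 (-0.99 ± 0.088), Cxcl10 (-0.82 ± 0.15), Ifit1bl1 (-1.06 ± 0.19) and Apol9b (-0.80 ± 0.18) fell.

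Of interferon response genes, 24 of 26 fell and 0 rose (26 and 0 adjusted over the list alone), median -0.53, adjusted p = 6.23e-63, with Irf7 at -0.55 ± 0.042 and Ifit1 at -0.65 ± 0.058. Of MHC class I genes, 12 of 15 fell and 0 rose, median -0.23, adjusted p = 1.51e-28, with H2-K1 at -0.31 ± 0.031. Of NRF2 targets, 8 of 12 rose and 0 fell (12 and 0 adjusted over the list alone), median 0.17, adjusted p = 1.27e-20, with Cat at 0.36 ± 0.021 and Gclm, for glutathione synthesis, at 0.24 ± 0.030. Of LXR targets, 2 of 18 rose (Mylip and Cd5l) and 0 fell (3 and 2 adjusted over the list alone), median 0.05, adjusted p = 0.0381 (adjusted p = 0.0686 with an estimated correlation). Of estrogen-responsive genes, 3 of 15 rose (Igfbp4, Ccnd1 and Nrip1) and 1 fell (Cxcl12, or 4 and 1 adjusted over the list alone), median 0.06, adjusted p = 0.0166 (adjusted p = 0.0841 with an estimated correlation), with Igfbp4, which binds insulin-like growth factors, at 0.42 ± 0.044. Of immediate early genes, 2 of 12 fell (Zfp36 and Junb) and 0 rose (3 and 1 adjusted over the list alone), median -0.05, adjusted p = 0.0364 (adjusted p = 0.109 with an estimated correlation), a downward test although the mean log2 fold change was 0.01. Of inflammatory genes, 5 of 21 fell (Ccl4, Ccl5, Ccl2, Ccl7 and Ccl3) and 0 rose (8 and 0 adjusted over the list alone), median -0.22, adjusted p = 6.17e-06 (adjusted p = 0.148 with an estimated correlation), with 8 fallen when E2 replicate 1 was left out. The glycolysis and hypoxia genes had a list median of 0.07 (adjusted p = 7.63e-04, or adjusted p = 0.110 with an estimated correlation), and Vegfa, an angiogenic factor, rose by 0.52. Cholesterol genes were not called as a list, where 1 of 25 rose (Hsd17b7) and 0 fell, median 0.01, adjusted p = 0.505. Nrip1 was not called (0.24 to 0.26) without Vehicle replicate 1 or E2 replicate 1, 2 or 5. Cxcl12 was not called (-0.12 to -0.11) without Vehicle replicate 4 or E2 replicate 4. Ccl3 was not called (-0.28 to -0.26) without Vehicle replicate 1 or 3 or E2 replicate 5. Hsd17b7 was not called (0.24 to 0.26) without Vehicle replicate 2 or E2 replicate 3 or 4.

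In total 305 genes rose and 345 fell with E2, or 4.70% of those tested, of which 5 rose and 7 fell at least 2-fold, and camera called 11 of 23 lists, 4 with an estimated correlation. Mitochondrial transcripts had a list median of 0.26 (adjusted p = 1.03e-08, or adjusted p = 0.0861 with an estimated correlation). Stromal markers were not called as a list, where 1 of 9 fell (Cxcl12) and 0 rose, median 0.03, adjusted p = 0.933.

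ICI was compared with Vehicle to measure an ER antagonist alone. Cholesterol genes fell with ICI, and so did glycolysis genes, while stress response and NRF2 genes rose. Idi1 fell 3.31-fold (log2 -1.73 ± 0.053, adjusted p = 2.17e-28), and Insig1 fell 2.24-fold (log2 -1.16 ± 0.035, adjusted p = 9.16e-29). Abcg1 rose 2.66-fold (log2 1.41 ± 0.069, adjusted p = 9.34e-21), and Lpl, the lipoprotein lipase gene, rose 2.38-fold (adjusted p = 6.03e-25). Il1b fell 6.21-fold (log2 -2.64 ± 0.17, adjusted p = 1.31e-16), and Mthfd2 rose 1.90-fold (log2 0.93 ± 0.033, adjusted p = 1.02e-25). Mylip (0.89 ± 0.035) and Cd5l (1.39 ± 0.045), a macrophage survival factor, rose, and Abca1 had a log2 fold change of -0.05 ± 0.063 (adjusted p = 0.614) and Srebf1 of -0.10 ± 0.049 (adjusted p = 0.155). Nr1h3 rose by 0.17 (0.15 to 0.16 and not called without Vehicle replicate 2 or 5 or ICI replicate 3 or 5, and 0.17 and not called without the low-count filter), Nr1h2 fell by 0.13 on the log2 scale, and Esr1 had -0.16 ± 0.10 (adjusted p = 0.285). High changes were in Tmem178 (1.75 ± 0.19), Soat2 (1.64 ± 0.18), which esterifies cholesterol, P2ry1 (1.55 ± 0.15), Efr3b (1.49 ± 0.097) and Cst7 (1.42 ± 0.088), and low ones in Adgre4 (-2.72 ± 0.13), Arg2 (-2.21 ± 0.16), an arginase, Fpr1 (-2.01 ± 0.11), a receptor for formyl peptides, and Pecam1 (-1.89 ± 0.11).

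Of cholesterol genes, 21 of 25 fell and 0 rose (22 and 0 adjusted over the list alone), median -0.76, adjusted p = 2.20e-34, with Sqle at -1.31 ± 0.050 and Hmgcs1 at -0.91 ± 0.038. LXR targets were not called as a list, where 6 of 18 rose and 3 fell (Arl4c, Scd2 and Apoe), median -0.02, adjusted p = 0.118. Of stress response genes, 14 of 19 rose and 1 fell (Slc7a11, or 15 and 1 adjusted over the list alone), median 0.52, adjusted p = 1.76e-17, with Atf4 at 0.64 ± 0.027 and Atf3 at 1.01 ± 0.050. Of NRF2 targets, 8 of 12 rose and 1 fell (Slc7a11), median 0.25, adjusted p = 1.13e-08, with Hmox1 at 0.48 ± 0.024. Of glycolysis and hypoxia genes, 13 of 18 fell and 1 rose (Ndrg1), median -0.19, adjusted p = 1.13e-08, with Ldha, lactate dehydrogenase, at -0.24 ± 0.027. Of PPAR targets, 5 of 12 rose (Fabp4, Cd36, Pparg, Plin2 and Fabp5) and 1 fell (Ucp2), median 0.12, adjusted p = 0.00457. Of inflammatory genes, 12 of 21 fell and 5 rose (Ccl4, Ccl5, Tnfaip3, Ccl3 and Tnf, or 13 and 5 adjusted over the list alone), median -0.49, adjusted p = 0.00457 (adjusted p = 0.399 with an estimated correlation). Of interferon response genes, 10 of 26 rose and 1 fell (Irf7, or 12 and 1 adjusted over the list alone), median 0.09, adjusted p = 0.0105 (adjusted p = 0.435 with an estimated correlation), with Rsad2 at 0.88 ± 0.048. Of macrophage identity genes, 9 of 13 fell and 4 rose (among them Cd68, Fcgr1 and Mertk), median -0.15, adjusted p = 0.00308 (adjusted p = 0.106 with an estimated correlation), with Lyz2, the lysozyme gene, at -0.88 ± 0.057. Estrogen-responsive genes were not called as a list, where 6 of 15 rose and 5 fell (Igfbp4, Cxcl12, Rara, Fhl2 and Cish), median 0.11, adjusted p = 0.0968, with Ccnd1 at 0.85 ± 0.045. In total 1925 genes rose and 1729 fell, among them 66 that rose and 87 that fell at least 2-fold, and camera called 10 of 23 lists, 5 with an estimated correlation. Stromal markers differed, where 7 of 9 fell and 0 rose, median -0.28, adjusted p = 2.62e-05 (adjusted p = 0.0522 with an estimated correlation). Mitochondrial transcripts took 1.98% ± 0.139 (SD, n = 5) of counts, and of their genes 9 of 13 rose and 0 fell (12 and 0 adjusted over the list alone), median 0.32, adjusted p = 4.79e-05 (adjusted p = 0.2 with an estimated correlation). Mertk was not called (0.09 to 0.11) without Vehicle replicate 3, 4 or 6 or ICI replicate 1 or 2. Cish was not called (-0.86 to -0.71) without Vehicle replicate 2, 3 or 5 or ICI replicate 3, 4 or 5.

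E2 and ICI, which share the estradiol core, were compared at unstated doses and times that may differ. Cholesterol synthesis and glycolysis genes were higher with E2 than with ICI, and interferon and stress response genes were lower. Hmgcs1 was 1.88-fold higher (log2 0.91 ± 0.039, adjusted p = 3.19e-23), with a 95% interval of 0.835 to 0.993 for the log2 fold change. F13a1 was 4.69-fold higher (log2 2.23 ± 0.082, adjusted p = 1.23e-25). Rsad2 was 3.04-fold lower (log2 -1.6 ± 0.052, adjusted p = 1.35e-27), and Abcg1 was 2.74-fold lower (log2 -1.45 ± 0.073, adjusted p = 2.83e-20). Adgre4 (3.05 ± 0.14), Il1b (2.23 ± 0.17), Fpr1 (2.05 ± 0.11) and Arg2 (1.98 ± 0.17) were higher, and Cst7 (-1.87 ± 0.096), Tmem178 (-2.03 ± 0.21) and Lpl (-1.38 ± 0.049) were lower. Esr1 (0.22 ± 0.11, adjusted p = 0.134) had an interval of 0 to 0.43, and Srebf1 (0.07 ± 0.051, adjusted p = 0.387) of -0.04 to 0.17, so neither differed by the test, although Esr1 was called (0.31) without E2 replicate 4. Nr1h2 (0.15 ± 0.038) was higher and Nr1h3 (-0.35 ± 0.062) lower with E2.

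Of cholesterol genes, 21 of 25 were higher and 0 were lower (22 and 0 adjusted over the list alone), median 0.80, adjusted p = 4.80e-32. Among interferon response genes, 25 of 26 were lower and 0 were higher (26 and 0 adjusted over the list alone), median -0.59, adjusted p = 1.96e-24. Of MHC class I genes, 13 of 15 were lower and 0 were higher, median -0.26, adjusted p = 1.61e-11. Of glycolysis genes, 14 of 18 were higher and 1 was lower (Ndrg1, or 15 and 1 adjusted over the list alone), median 0.24, adjusted p = 3.94e-11, with Vegfa at 0.94 ± 0.055. Of stress response genes, 14 of 19 were lower and 1 was higher (Slc7a11), median -0.44, adjusted p = 3.74e-16, with Atf4 at -0.78 ± 0.028. Among macrophage identity genes, 8 of 13 were higher and 4 were lower (among them Fcgr1, Cd68 and Mertk), median 0.11, adjusted p = 0.0215 (adjusted p = 0.180 with an estimated correlation), with Cd14 at 1.06 ± 0.041. LXR targets were not called as a list, where 6 of 18 were lower and 5 were higher (Arl4c, Scd2, Apoe, Fasn and Abca1, or 6 and 7 adjusted over the list alone), median 0.08, adjusted p = 0.357, nor were estrogen-responsive genes, where 6 of 15 were lower and 4 were higher (Igfbp4, Cxcl12, Rara and Fhl2), median 0.11, adjusted p = 0.357, with Igfbp4 at 0.85 ± 0.047. In total 1812 genes were higher and 1988 lower with E2, among them 94 higher and 71 lower at least 2-fold, and camera called 7 of 23 lists, 5 with an estimated correlation. Of stromal markers, 8 of 9 were higher and 0 were lower, median 0.23, adjusted p = 4.55e-05 (adjusted p = 0.0649 with an estimated correlation), with Col3a1 at 0.88 ± 0.077. In this comparison the mitochondrial transcripts had a list median of -0.11 (adjusted p = 0.357, or adjusted p = 0.732 with an estimated correlation). Mertk was not called (-0.13 to -0.08) without E2 replicate 3, 4 or 5 or ICI replicate 1, 2, 3 or 5. Fasn was not called (0.27 to 0.28) without E2 replicate 4 or 5 or ICI replicate 4. Abca1 was not called (0.13 to 0.18) without E2 replicate 1 or 2 or ICI replicate 1, 3, 4 or 5.

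GSK2033 with 27HC was compared with 27HC alone to ask what the LXR antagonist changes in the presence of the oxysterol. LXR targets were far lower with the antagonist present, and macrophage identity and cell cycle genes were lower too, while interferon, antigen presentation, stress response and NRF2 genes were higher. Abcg1 fell 464-fold (log2 -8.86 ± 0.12, adjusted p = 1.57e-41), from 342 ± 15.7 to 0.737 ± 0.145 CPM, and Abca1 fell 25.1-fold (log2 -4.65 ± 0.078, adjusted p = 2.38e-38). Slc7a11 rose 6.52-fold (log2 2.70 ± 0.082, adjusted p = 3.59e-29). The complement gene C1qc fell 2.11-fold (log2 -1.08 ± 0.030, adjusted p = 7.06e-31). Mylip (-3.78 ± 0.043), Scd2 (-3.81 ± 0.050), Eepd1 (-3.75 ± 0.064) and Cd38 (-3.35 ± 0.14), which hydrolyses NAD, fell, and H2-M2 (3.07 ± 0.081), Cox6a2 (3.38 ± 0.20), Gbp8 (2.81 ± 0.33), Cdsn (2.80 ± 0.20) and Slfn1 (2.69 ± 0.14) rose. Esr1 rose by 0.44, and Nr1h2 (0.06 ± 0.038, adjusted p = 0.236) and Nr1h3 (0.10 ± 0.064, adjusted p = 0.205) were not called, although both were (0.11 and 0.15) with library totals only.

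Of LXR targets, 17 of 18 fell and 0 rose, median -1.38, adjusted p = 3.49e-23. Of fatty acid synthesis genes, 10 of 15 fell and 2 rose (Acss2 and Me1), median -0.57, adjusted p = 2.29e-05. Cholesterol genes went both ways: 9 of 25 rose and 8 fell (10 and 9 adjusted over the list alone), median 0.02, adjusted p = 0.428, with Hmgcs1, whose libraries overlapped, at 0.14 ± 0.041 (adjusted p = 0.00579), or 0.10 and not called without 27HC replicate 1. Among interferon response genes, 24 of 26 rose and 0 fell (25 and 0 adjusted over the list alone), median 0.96, adjusted p = 7.15e-22, with Ifit1 at 1.78 ± 0.067. Of MHC class I genes, 12 of 15 rose and 1 fell (Calr, or 13 and 1 adjusted over the list alone), median 0.49, adjusted p = 7.23e-10, and of MHC class II genes, 7 of 12 rose and 2 fell (H2-DMb2 and H2-DMa, or 8 and 2 adjusted over the list alone), median 0.52, adjusted p = 0.00599. Of inflammatory genes, 15 of 21 rose and 4 fell (Il1a, Saa3, Il1b and Nfkbiz), median 0.56, adjusted p = 1.32e-05 (adjusted p = 0.156 with an estimated correlation), with Icam1, an adhesion molecule, at 1.04 ± 0.045. Among macrophage identity genes, 11 of 13 fell and 1 rose (Adgre1), median -0.49, adjusted p = 2.09e-11. Of cell cycle genes, 13 of 26 fell and 0 rose, median -0.30, adjusted p = 4.47e-04, with Pcna at -0.73 ± 0.040. Of stress response genes, 18 of 19 rose and 1 fell (Atf3), median 0.68, adjusted p = 1.24e-17, with Trib3 at 2.13 ± 0.052. Of NRF2 targets, 10 of 12 rose and 1 fell (Osgin1), median 0.59, adjusted p = 8.49e-10, with Prdx1, a peroxidase, at 1.07 ± 0.034. Igf1 fell by 1.03 on the log2 scale. In total 2923 genes rose and 2998 fell, among them 320 that rose and 254 that fell at least 2-fold, and camera called 13 of 23 lists, 10 with an estimated correlation. With library totals only, 61.1% of the called genes were higher, against 49.4% with scaling factors. With GSK2033 added, mitochondrial transcripts had a list median of -0.53 (adjusted p = 8.80e-06, or adjusted p = 0.144 with an estimated correlation). Calr was not called (-0.06 to -0.04) without GSK2033 plus 27HC replicate 1, 2 or 3. H2-DMa was not called (-0.16 to -0.15) without GSK2033 plus 27HC replicate 2 or 4. Il1b was not called (-0.44 to -0.42) without 27HC replicate 2 or GSK2033 plus 27HC replicate 4. Nfkbiz was not called (-0.21 to -0.17) without 27HC replicate 1, 2 or 4 or GSK2033 plus 27HC replicate 1, 4 or 5.

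The interaction of GSK2033 and 27HC asks whether the response to 27HC differed with and without the antagonist, as a difference of log2 fold changes. Cholesterol genes lay above 0, their fall with 27HC being smaller with GSK2033, and LXR targets lay below 0. Insig1 (1.69 ± 0.051, adjusted p = 3.25e-28), Sqle (1.83 ± 0.076) and Idi1 (1.88 ± 0.083) lay above 0. Abcg1 (-3.92 ± 0.29, adjusted p = 2.69e-14), Abca1 (-2.19 ± 0.098), Scd2 (-2.11 ± 0.070), Mylip (-1.44 ± 0.066) and Nr1h3 (-0.60 ± 0.086) lay below 0, and Nr1h2 (-0.06 ± 0.053) and Esr1 (0.37 ± 0.15, adjusted p = 0.0755) were not called. Esr1 was called without GSK2033 replicate 4 (0.46) or GSK2033 plus 27HC replicate 3 (0.43), with library totals only (0.42) and with the stricter filter (0.40). With both compounds Abcg1 was at 0.737 ± 0.145 CPM, so its value rests on low counts. Of cholesterol genes, 21 of 25 lay above 0 and 1 lay below 0 (Ebp, or 22 and 1 adjusted over the list alone), median 0.95, adjusted p = 2.19e-37. Of LXR targets, 13 of 18 lay below 0 and 0 lay above 0, median -0.69, adjusted p = 8.66e-26. Among interferon response genes, 21 of 26 lay above 0 and 0 lay below 0, median 0.38, adjusted p = 3.65e-15. Among macrophage identity genes, 8 of 13 lay below 0 and 3 lay above 0 (Lyz2, Itgam and Adgre1), median -0.27, adjusted p = 8.03e-08, with C1qa at -0.65 ± 0.047. Of cell cycle genes, 6 of 26 lay below 0 and 0 lay above 0, median -0.14, adjusted p = 0.00140. Of immediate early genes, 8 of 12 lay below 0 and 1 lay above 0 (Ier3), median -0.29, adjusted p = 4.96e-05, with Zfp36, which destabilises messenger RNA, at -0.91 ± 0.051. Ebp was not called (-0.24 to -0.17) without Vehicle replicate 1, 2, 3, 4 or 6, 27HC replicate 3, 4 or 5, GSK2033 replicate 1, 2, 3 or 4 or GSK2033 plus 27HC replicate 2, 3 or 4.

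Of glycolysis genes in this interaction, 10 of 18 lay above 0 and 0 lay below 0 (12 and 0 adjusted over the list alone), median 0.20, adjusted p = 1.01e-06. Among stress response genes, 10 of 19 lay above 0 and 4 lay below 0 (Atf3, Xbp1, Mthfd2 and Sdf2l1, or 12 and 4 adjusted over the list alone), median 0.15, adjusted p = 0.00617. Of NRF2 targets, 7 of 12 lay above 0 and 2 lay below 0 (Hmox1 and Gclc), median 0.22, adjusted p = 7.40e-04. In this interaction, mitochondrial transcripts had a list median of -0.31 (adjusted p = 0.00172, or adjusted p = 0.343 with an estimated correlation). In total 1292 genes lay above 0 and 1420 below, among them 103 above and 59 below by at least 1 on the log2 scale, and camera called 12 of 23 lists, 10 with an estimated correlation. With library totals only, 63.2% of the called genes lay above 0, against 47.6% with scaling factors.

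ICI with 27HC was compared with 27HC alone to ask what the ER antagonist changes with 27HC present. Stress response and NRF2 genes rose, and macrophage identity and cell cycle genes fell. Atf4 rose 2.69-fold (log2 1.43 ± 0.028, adjusted p = 1.00e-35), and Gdf15 rose 4.71-fold (log2 2.24 ± 0.049, adjusted p = 1.99e-34). Itgam fell 2.14-fold (log2 -1.10 ± 0.038, adjusted p = 5.64e-27), and Il1b fell 5.55-fold (log2 -2.47 ± 0.22, adjusted p = 2.24e-12). Cd274 rose 2.32-fold (log2 1.21 ± 0.055, adjusted p = 1.35e-22). Abca1 fell by 0.48 on the log2 scale, and Abcg1 had a log2 fold change of -0.05 ± 0.065 (adjusted p = 0.595). Nr1h2 (-0.12 ± 0.038), Nr1h3 (-0.24 ± 0.065) and Esr1 (-0.61 ± 0.12) fell, with overlapping libraries for Nr1h3. Mt2 (2.1 ± 0.076), a metallothionein gene, and Aqp9 (2.02 ± 0.21) rose, and Fpr1 (-2.66 ± 0.16), Ms4a4a (-2.58 ± 0.12), Ppbp (-2.46 ± 0.19), Adgre4 (-2.79 ± 0.23) and F13a1 (-2.33 ± 0.095) fell.

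Among stress response genes, 18 of 19 rose and 0 fell, median 0.77, adjusted p = 3.36e-26, with Trib3 at 1.96 ± 0.052 and Asns, which makes asparagine, at 1.40 ± 0.052. Of NRF2 targets, 11 of 12 rose and 0 fell, median 0.51, adjusted p = 6.74e-17, with Srxn1 at 0.88 ± 0.022. Among macrophage identity genes, 12 of 13 fell and 1 rose (Cd68), median -0.54, adjusted p = 2.15e-15, with Csf1r, the receptor for macrophage colony-stimulating factor, at -0.54 ± 0.022. Of cell cycle genes, 16 of 26 fell and 1 rose (Pcna, or 17 and 1 adjusted over the list alone), median -0.37, adjusted p = 1.93e-05, with Mcm5 at -0.56 ± 0.057. Of LXR targets, 10 of 18 fell and 4 rose (Cd5l, Lpl, Mylip and Fasn), median -0.24, adjusted p = 0.0235. Cholesterol genes were not called as a list, where 7 of 25 rose and 4 fell (Stard4, Tm7sf2, Ebp and Acat2), median 0.07, adjusted p = 0.441. Of PPAR targets, 7 of 12 rose and 4 fell (among them Ucp2, Cpt1a and Cd36), median 0.23, adjusted p = 0.0235 (adjusted p = 0.0591 with an estimated correlation), with Fabp4, a fatty acid carrier, at 1.54 ± 0.060. In total 2319 genes rose and 2403 fell, among them 107 that rose and 172 that fell at least 2-fold, and camera called 10 of 23 lists, 5 with an estimated correlation. Stromal markers differed, where 6 of 9 fell and 0 rose, median -0.21, adjusted p = 0.00907 (adjusted p = 0.218 with an estimated correlation). With ICI added, mitochondrial transcripts had a list median of -0.21 (adjusted p = 0.0235, or adjusted p = 0.515 with an estimated correlation).

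In the ICI and 27HC interaction, cholesterol, stress response and NRF2 genes lay above 0, and LXR targets below. Sqle (1.67 ± 0.075, adjusted p = 1.12e-21), Slc7a11 (1.65 ± 0.12) and Gdf15 (1.62 ± 0.069) lay above 0. Abcg1 (-1.47 ± 0.095, adjusted p = 5.50e-16), Mylip (-0.73 ± 0.049), Nr1h3 (-0.41 ± 0.088), Esr1 (-0.45 ± 0.16) and Cx3cr1 (-1.69 ± 0.11), the fractalkine receptor gene, lay below 0, and Nr1h2 had 0.01 ± 0.053. ICI alone raised Abcg1 and Mylip, so their response to 27HC started from a higher level with ICI. Esr1 (adjusted p = 0.0373) was not called, at -0.45 to -0.41, without Vehicle replicate 2 or 4, 27HC replicate 2, 3 or 5, ICI replicate 2, 3 or 5, or ICI plus 27HC replicate 1, 2, 3 or 5, nor with library totals only (-0.42) or no low-count filter (-0.45). Of cholesterol genes, 18 of 25 lay above 0 and 0 lay below 0 (20 and 1 adjusted over the list alone), median 0.73, adjusted p = 5.22e-34. Of LXR targets, 10 of 18 lay below 0 and 1 lay above 0 (Fasn, or 11 and 1 adjusted over the list alone), median -0.36, adjusted p = 2.90e-08. Among stress response genes, 13 of 19 lay above 0 and 4 lay below 0 (Sdf2l1, Hspa5, Xbp1 and Hsp90b1), median 0.36, adjusted p = 4.09e-10. Of NRF2 targets, 8 of 12 lay above 0 and 0 lay below 0, median 0.27, adjusted p = 1.88e-09. Among macrophage identity genes, 10 of 13 lay below 0 and 2 lay above 0 (Lyz2 and Cd14), median -0.36, adjusted p = 9.19e-13. Of cell cycle genes, 11 of 26 lay below 0 and 0 lay above 0, median -0.34, adjusted p = 2.90e-06. Hsp90b1 was not called (-0.13 to -0.10) without Vehicle replicate 2, 3, 4, 5 or 6, 27HC replicate 1, 2, 3 or 4, ICI replicate 1, 2 or 5 or ICI plus 27HC replicate 3, 4 or 5.

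Here mitochondrial transcripts had a list median of -0.55 (adjusted p = 5.72e-09, or adjusted p = 0.0833 with an estimated correlation). In total 1023 genes lay above 0 and 1380 below, among them 56 above and 64 below by at least 1 on the log2 scale, and camera called 11 of 23 lists, 6 with an estimated correlation. With library totals only, 54.2% of the called genes lay above 0, against 42.6% with scaling factors.

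GW3965 with the second compound was compared with GW3965 alone. Cholesterol, fatty acid synthesis and LXR target genes fell, and stress response, MHC class II and interferon genes rose. Insig1 fell 2.74-fold (log2 -1.46 ± 0.035, adjusted p = 1.77e-32), and Scd2 fell 2.23-fold (log2 -1.16 ± 0.039, adjusted p = 1.04e-26). Trib3 rose 2.1-fold (log2 1.07 ± 0.051, adjusted p = 4.52e-21), and H2-Aa, an MHC class II chain, rose 1.75-fold (log2 0.81 ± 0.060, adjusted p = 1.31e-14). Abca1 had a log2 fold change of -0.22 ± 0.065 (adjusted p = 0.0126) and Abcg1 of -0.20 ± 0.064 (adjusted p = 0.0207). Nr1h2 (-0.16 ± 0.038) and Nr1h3 (-0.22 ± 0.065) fell with overlapping libraries, and Esr1 (0.45 ± 0.12) rose. Abca1 was not called without GW3965 replicate 4 (-0.17), nor Abcg1 without GW3965 replicate 4 (-0.19) or 5 (-0.18) or replicate 3 of the combination (-0.18). Nr1h3 was not called without GW3965 replicate 5 (-0.15) or without replicate 2 (-0.19) or 5 (-0.18) of the combination. Fads2 (-1.96 ± 0.096), Scd1 (-1.59 ± 0.075), Srebf1 (-0.74 ± 0.047) and Fpr1 (-1.66 ± 0.19) fell, and Cst7 (1.20 ± 0.12), Cox6a2 (1.98 ± 0.19), Aqp9 (1.49 ± 0.23) and Ifi206 (1.17 ± 0.16) rose.

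Of cholesterol genes, 22 of 25 fell and 0 rose (23 and 0 adjusted over the list alone), median -0.69, adjusted p = 3.78e-47. Of fatty acid synthesis genes, 12 of 15 fell and 0 rose, median -0.44, adjusted p = 2.68e-18. Of LXR targets, 11 of 18 fell and 2 rose (Cd5l and Lpl), median -0.22, adjusted p = 1.54e-08. Among stress response genes, 18 of 19 rose and 0 fell (19 and 0 adjusted over the list alone), median 0.36, adjusted p = 3.74e-32, with Atf4 at 0.69 ± 0.028. Of MHC class II genes, 7 of 12 rose and 0 fell (8 and 0 adjusted over the list alone), median 0.36, adjusted p = 1.61e-08. Among interferon response genes, 16 of 26 rose and 0 fell, median 0.35, adjusted p = 1.18e-12, with Rsad2 at 0.77 ± 0.061. For macrophage identity genes, 7 of 13 fell and 2 rose (Cd68 and Fcgr1, or 8 and 2 adjusted over the list alone), median -0.11, adjusted p = 1.78e-05, with Cd14 at -1.23 ± 0.043. In total 1097 genes rose and 1323 fell, among them 41 that rose and 57 that fell at least 2-fold, and camera called 12 of 23 lists, 8 with an estimated correlation. With library totals only, 58.7% of the called genes were higher, against 45.3% with scaling factors. Stromal markers differed, where 7 of 9 fell and 0 rose, median -0.20, adjusted p = 6.43e-05 (adjusted p = 0.0543 with an estimated correlation), with Sparc at -0.27 ± 0.031. With the second compound, mitochondrial transcripts had a list median of -0.32 (adjusted p = 1.61e-06, or adjusted p = 0.141 with an estimated correlation).

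Few markers of neutrophils (1 of 12), lymphocytes (3 of 12) and erythroid cells (1 of 8) had enough counts for testing, while 9 of 10 stromal and 5 of 8 osteoclast markers did. With 27HC, 1 of 3 fell (Cd4) and 0 rose (2 and 0 adjusted over the list alone), median -0.31, adjusted p = 0.181 among lymphocyte markers, 2 of 4 rose (Itgax and Batf3) and 0 fell, median 0.32, adjusted p = 0.362 among dendritic cell markers, 0 of 3 rose and 0 fell, median -0.19, adjusted p = 0.652 among mast cell and basophil markers, and 3 of 5 fell (Acp5, Ctsk and Mmp9) and 1 rose (Dcstamp, or 4 and 1 adjusted over the list alone), median -0.47, adjusted p = 0.0717 among osteoclast markers. A single neutrophil marker, S100a8, was tested, and a single erythroid marker, Epor, with log2 medians of -0.25 and 0.29 with 27HC. S100a8 fell with GW3965 (list median -0.95). Batf3 was not called (0.48 to 0.69) without Vehicle replicate 4, 5 or 6 or 27HC replicate 2, 3 or 4.

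**Figure D4:**
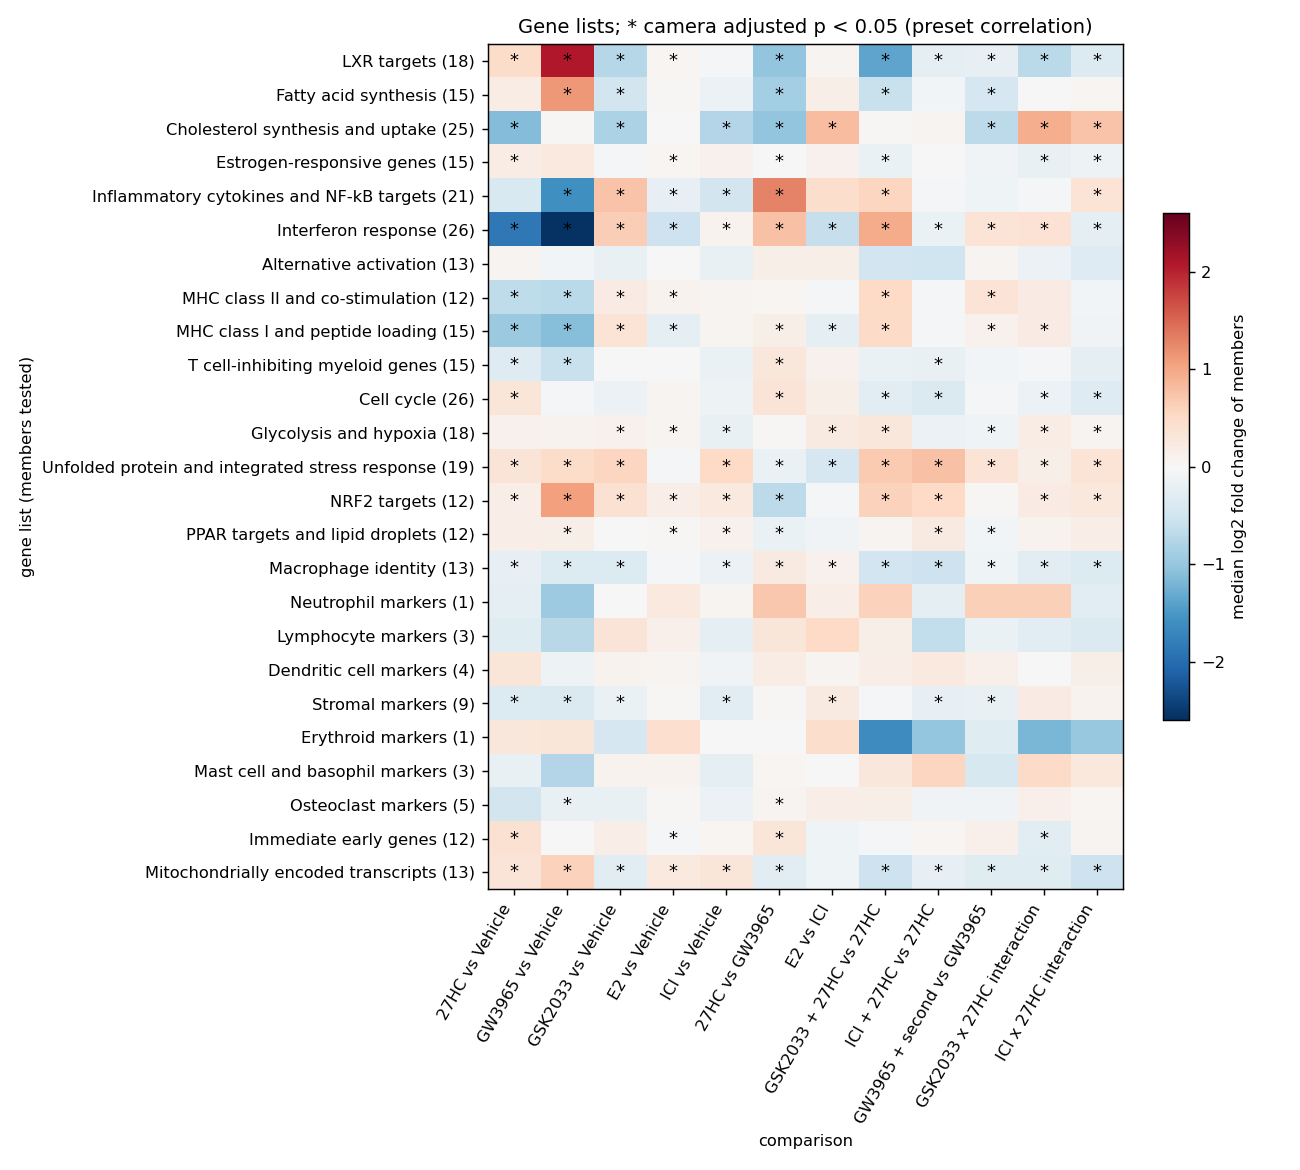
Median log2 fold change of each of 25 gene lists (vertical) in each of 12 comparisons (horizontal), with an asterisk where camera with a preset correlation gives an adjusted p under 0.05. Interferon genes have medians of -1.86 with 27HC and -2.56 with GW3965, and cholesterol genes have -1.12 with 27HC, 0.02 with GW3965 and -0.76 with ICI.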

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

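The tests of explanations here and the comparison with other splits were written after the results were seen, while the interactions were planned.

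To ask whether chance gives as many calls, fits on the groups compared alone were repeated on 100 splits of their libraries. In each of the 12 comparisons only the real split, 1 of the 100, gave as many calls, the smallest share possible. The median of the others was 0 calls in each. For a pair of groups this argues against a chance division, but not against a culture or handling effect. Against Vehicle (n = 6), a split can set the 5 treated and 1 Vehicle library against the rest, nearly the real contrast. So there the highest other counts may not measure chance. The real split against the highest other split gave 5213 and 3218 genes for 27HC against Vehicle, 5860 and 4071 for GW3965, 4814 and 3228 for GSK2033, 476 and 228 for E2, and 3154 and 1790 for ICI. It gave 3078 and 1 for 27HC against GW3965, 3353 and 1 for E2 against ICI, 5629 and 1 for GSK2033 added to 27HC, 4304 and 1 for ICI added to 27HC, and 1931 and 1 for the second compound added to GW3965. The interactions gave 2637 and 878 with GSK2033, and 2188 and 9 with ICI. Those splits mix all the groups, also removing each compound's own effect, so they cannot decide whether an interaction arises by chance.

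The response to 27HC differed with and without an antagonist, by the interaction test of edgeR, in 2712 genes for GSK2033 and in 2403 genes for ICI. The interaction with GSK2033 was -0.60 for Nr1h3, -2.19 for Abca1, -3.92 for Abcg1, -1.44 for Mylip and 1.14 for Hmgcs1 on the log2 scale. With ICI it was -0.41 for Nr1h3, -0.45 for Esr1, -0.43 for Abca1, -1.47 for Abcg1, -0.73 for Mylip and 1.06 for Hmgcs1.

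The smaller response of the cholesterol genes to 27HC with GSK2033 or ICI was weighed first. Counts near 0 that limit a further fall are argued against, since 0.0% of the 25 genes had a mean below 10 counts with 27HC and the lowest mean was 54.2. Whether these genes reach a like level with 27HC whatever their level before stays open. The median absolute log2 difference from the libraries without antagonist was 0.273 with 27HC against 0.826 without it for GSK2033, a ratio of 0.331, and 22 of 25 genes were closer. For ICI the values were 0.143 and 0.757, a ratio of 0.189, with 23 of 25 closer. These values do not decide it, because the difference with 27HC is the effect of the antagonist alone plus the interaction, and so restates the smaller response. With 27HC present, 9 of 25 genes were still higher and 8 lower with GSK2033, and 7 higher and 4 lower with ICI. An action of each antagonist on the 27HC pathway itself stays open and was not tested.

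The fall of cholesterol genes with ICI alone was weighed next. Carry-over of 27HC into the ICI libraries is argued against in so far as it would lower interferon genes by a like share. The median ratio of the ICI change to the 27HC change was 0.645 (95% bootstrap interval 0.597 to 0.693, with libraries resampled within groups) for cholesterol genes and -0.048 (-0.079 to -0.031) for interferon genes. The test leaves open an amount of 27HC that lowers cholesterol genes only, or an ICI effect on interferon genes that hides a fall. An effect through the estrogen receptor that E2 moves the other way is argued against by the median change of these genes with E2, 0.007 (-0.017 to 0.059, from the same resampling of libraries), and library size or scaling by 21 genes still called lower under the scaling that gave fewest. A direct effect of the compound, or a receptor effect that added E2 does not oppose, may account for the fall and stays open.

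The compound added to GW3965, which the labels name as 27HC and as ICI, was weighed last. In 69 genes 27HC and ICI were called in opposite directions against Vehicle, each kept its direction when added to the other, and 27HC lay beyond GW3965, and 33 of these changed when the second compound was added. Of the 33, 3 followed 27HC (9.1%, 95% Wilson interval 3.1 to 23.6) and 30 followed ICI (90.9%, 76.4 to 96.9). The 33 genes are not independent replicates, so these intervals do not measure the spread between libraries. Without the condition on GW3965, 98 of 103 changed genes followed ICI. The values argue against 27HC and go with ICI, which may be the compound used, but a response to 27HC that GW3965 alters stays open and the group keeps its unnamed second compound.

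Single libraries stood apart from the others of their group in 10 of the 108 group measurements tested with Dixon's criterion, where chance gives about 1 in 20, or 5.4. Some of the genes followed were left out of this count and of the interactions above after the tests had been run. In CPM the libraries apart were Abca1 in ICI replicate 2 (409.5), Nr1h2 in ICI plus 27HC replicate 3 (76.29), and Srebf1 in GSK2033 plus 27HC replicate 5 (63.83). Nr1h3 stood apart in GW3965 replicate 5 (51.15) and in replicate 3 of GW3965 plus the second compound (46.35). Esr2, near the limit of detection, stood apart in Vehicle replicate 6 (0.2013), in ICI plus 27HC replicate 3 (0.1816) and in replicate 1 of GW3965 plus the second compound (0.0). The percentage of counts in the 10 most abundant genes stood apart in GSK2033 replicate 4 (10.75) and GSK2033 plus 27HC replicate 2 (11.533).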

How the results depend on the processing

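The alternative without mitochondrially encoded genes was chosen after seeing the data, and the others were planned. The numbers of genes higher and lower in the 12 comparisons stayed within 1.5 times their reported counts with RLE factors, library totals only, no low-count filter, a CPM of at least 5 in at least 5 libraries, a replicate block, only the groups compared, limma-trend, DESeq2, no mitochondrially encoded genes, and each library left out in turn. Alternatives for normalized values were not run, because the values are counts. With a replicate block, which takes libraries of the same number as paired, 27HC against Vehicle had 2824 genes higher and 2782 lower, and E2 against Vehicle 434 and 409. Over 180 pairs of libraries with the same number in different groups, residuals had a mean r of 0.012 and a highest r of 0.1. The mean r was -0.003 over 760 pairs with different numbers. Of 45 libraries, 12 had their highest mean r with the libraries of their own number in other groups. The fit that does not take the numbers as pairs had been planned. With library totals only, and beside the comparisons where the report gives it, the side with more calls turned: 46.7% of called genes were higher against 52.3% with scaling factors for GW3965, 44.9% against 52.7% for ICI, 51.1% against 47.7% for E2 against ICI, and 53.8% against 49.1% for ICI added to 27HC. The widest relative change over these counts was in genes higher with E2, 212 against 305 when only the groups compared were fitted. With each library left out in turn, the genes higher and lower ranged from 2631 to 2735 and from 2546 to 2679 for 27HC, from 2867 to 3149 and from 2795 to 2963 for GW3965, and from 239 to 328 and from 268 to 343 for E2. With a correlation estimated per list, the lists called went from 13 to 8 for GSK2033, from 11 to 4 for E2, from 10 to 5 for ICI, from 10 to 5 for ICI added to 27HC, and from 11 to 6 for the ICI interaction, since a higher correlation between members widens the test's spread. Of 12296 values of named genes under other settings, 119 lost their call, 51 gained one and 0 reversed, and of 16924 with a library left out, 312 lost it, 55 gained one and 0 reversed. Depth limits genes with few counts, such as Esr2 with 0 to 7 counts per library.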

Other observations

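In a principal component analysis of log2 CPM over the 46 libraries, the first components took 26.4%, 11.9%, 4.7% and 3.5% of the variance. The 10 most abundant genes took 10.5% ± 0.180 (SD, n = 6) of counts with Vehicle and 11.9% ± 0.211 (SD, n = 5) with GW3965 plus the second compound. Across all 13838 genes, which are not independent replicates, the change on adding the second compound to GW3965 had an r of 0.279 with the change on adding ICI to 27HC, and of 0.068 with the change on adding 27HC to ICI.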
